A study of Mus musculus with 39 samples.

How the data were processed

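Total RNA from the livers of adult male mice of the 129SV background was measured on Applied Biosystems Mouse Genome Survey arrays. Per the labels' protocols, wild-type and PPARα-null mice received PFOA (perfluorooctanoic acid, as its ammonium salt) at 0, 1 or 3 mg/kg in deionised water, or pirinixic acid, a synthetic activator of PPARα that the labels give by its Wyeth code number, at 0 or 50 mg/kg in 0.5% methylcellulose. Dosing was by gavage on 7 consecutive days. Per the labels' protocols, RNA was used only with an integrity number of at least 8.5, and digoxigenin-labelled cRNA was made from total RNA with 1 round of amplification. The labels name 4 animals per group. The deposited table holds 39 arrays in 10 groups: 9 groups have 4 arrays, and wild type with methylcellulose has 3.

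The deposited values are log2 signals to which the authors had given equal quantiles on every array, apart from missing values, as quantile normalisation does; this was read from the values. The base of the logarithm is not written in the labels and is taken as 2 from the range of the values, 4.85 to 21.5, which corresponds to linear signals of 28.8 to 3069562. The median was 9.14 on every array. The software, the normalisation steps, the background correction and the reason for missing values are not given in the sources used here. No further normalisation was applied in the fit that gives the values of the report.

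The table has 33012 probes. The probe-gene table names 1 gene for 14411 of them, several genes for 247 and none for 18354. Of the probes with 1 gene, 14402 were matched to the gene annotation by their Entrez number, and 0 symbols were updated. The table lacks 14823 values (1.15%), between 202 and 839 per array. The 25295 probes with a value on all 39 arrays were tested. The 7717 probes with a missing value were left out of the main counts because a missing value leaves a group with fewer arrays; the median of their mean signals was 7.56, against 9.95 for the tested probes. Among the tested probes, 12029 have 1 gene symbol, covering 11591 genes, and 203 have several. Probes with no symbol count in the totals but cannot be named. Cyp4a10 and Cyp3a11 are each covered only by 1 probe shared with other genes, so neither gene has a value here.

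The log2 values of all 39 arrays were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and empirical Bayes moderation of the variances (29 residual and 2.51 prior degrees of freedom). 17 differences were tested: each of the 6 treated groups against its vehicle, the null response minus the wild-type response for each of the 3 treatments, 3 against 1 mg/kg PFOA in each genotype, the PFOA 3 mg/kg response minus the pirinixic acid response in each genotype, null against wild type in each vehicle, and methylcellulose against water in each genotype. A probe was counted as changed with a Benjamini-Hochberg adjusted p under 0.05 over the 25295 probes of that difference. The tests are two-sided. With no change at any probe, about 0.05 of the 25295 probes would still have an unadjusted p under 0.05, so counts at that limit are not counts of changed probes. Errors given with a log2 difference are standard errors of the limma fit, and those given with a group mean are standard deviations. 3 counts of probes changed in the same direction by a pair of treatments were also made, each beside the overlap that independent lists of the same sizes would have in each direction. The number of arrays limits the precision of every value.

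The genes named were chosen by a rule fixed before the data were examined. For each treated group against its vehicle, the rule takes up to 10 rises and 10 falls, the largest on the log2 scale, among probes with 1 gene symbol, an adjusted p under 0.05, every treated array on the same side of the control mean, and the higher group's mean above the median of all probes. For the differences between genotypes and between compounds it takes up to 5 in each direction, and for those between doses and vehicles up to 3; the condition on every array was not used where 4 groups enter. Up to 4 members of each gene list, those with the smallest adjusted p, were added. Ppara, Ehhadh, Cyp4a10, Cyp4a14, Pdk4, Cyp2b10, Cyp3a11, Cyp2c55, Nr1i3, Cyp7a1 and Fgf21 were always to be reported, and so was 1 more gene that is not reported here. A gene with several probes is given by the probe with the highest mean, and symbols that only number a clone were passed over. Names at the bottom of a ranking may be left out.

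21 gene lists were fixed in advance: peroxisomal beta-oxidation and biogenesis, mitochondrial beta-oxidation and ketogenesis, omega-oxidation and fatty acid handling, CAR and PXR xenobiotic metabolism, NRF2 and glutathione, AhR targets, cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, bile acid synthesis and transport, lipoproteins and HDL metabolism, glucose and glycogen metabolism, amino acid catabolism and urea cycle, acute phase, complement and coagulation, proteasome, chaperones and unfolded protein response, cell cycle, p53 and DNA damage, male-biased and female-biased liver genes, and oxidative phosphorylation. 10 lists of cell markers were fixed with them: Kupffer cell and macrophage, stellate cell and fibroblast, endothelial cell, cholangiocyte, lymphocyte, neutrophil, red blood cell, pancreas acinar cell, adipocyte, and hepatocyte. Some genes stand on a pair of lists: C8b and C6 on complement and male-biased, Slco1a1 on bile acid and male-biased, Gstp1 on NRF2 and male-biased, and Cyp2b13 and Cyp3a44 on CAR and PXR and female-biased. Each list was tested in the 6 treated groups with limma's camera at a preset correlation of 0.01, on 1 probe per gene and against all other named genes, and the p-values were adjusted over the 126 tests of gene lists and the 60 of marker lists. The same tests were run on the 3 null-minus-wild-type differences as a separate family. Counts of list members use the adjustment over all probes, with the count adjusted over the list alone beside them.

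Alternatives planned in advance were centring each array on its 75th percentile, leaving out the probes with a mean below the median, an intensity trend in the prior variance, 1 probe per gene, a minimum change of 1.5-fold, the replicate number as a block, only the arrays of the groups compared, leaving out each array in turn, camera with an estimated correlation, and fry, a test of whether a list's genes move on balance one way. A different log scale was planned for linear values and was not run, because the values are log2. 8 alternatives were added after the data were seen. They use array set as a block or only the arrays of 1 set, leave out the array labelled wild type, PFOA 1 mg/kg, replicate 3, allow missing values with at least 2 values in every group, or take an index of clock genes or of genes silent in liver as a covariate, some of them together. Array set means the division of the arrays into 16 and 23 that was found from probes with a gap of at least 1 log2 unit and at least 8 arrays on each side; the labels give no batch. Correlations across arrays were tested with 100000 permutations of seed 1, and other assignments of the same arrays to groups were counted in full up to 100 splits, and in 100 drawn at random beyond that. The replicate numbers were not taken to pair the arrays, because the labels name no shared animal or batch and not every pair deviated together: over 171 pairs with the same number the deviations from the group means correlated by -0.263 to 0.479, with 86 over 0.1. Arrays with the same number were still more alike than others (mean r of 0.0884 against -0.0292), and 27 of 39 arrays were nearest to one of their own number. The scripts were tested on simulated data with the design of the wild-type PFOA 3 mg/kg comparison: of 100 probes changed by log2 1 the fit recovered 44%, and of 100 changed by log2 2 it recovered 75%, with 4 false calls among 125.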

Results

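The data are 39 liver arrays from male wild-type and PPARα-null mice after 7 days of gavage. In each genotype there are 4 arrays for each of water, PFOA 1 mg/kg, PFOA 3 mg/kg and 50 mg/kg of pirinixic acid, which the labels and the plots give by its Wyeth code number. The methylcellulose vehicle has 4 arrays in null and 3 in wild-type mice. Every array gives a log2 signal for most of 33012 probes, and 25295 probes with a value on all arrays were tested. Across these probes the correlation between arrays of the same group had a median of 0.958 (0.928 to 0.974 over 57 pairs), and that between arrays of different groups a median of 0.952 (0.904 to 0.977 over 684 pairs). The series asks which liver responses to PFOA need PPARα, the nuclear receptor for fatty acids that pirinixic acid activates, and compares PFOA with pirinixic acid.

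The targeted gene itself was measured by a probe with signal in every group. Ppara averaged 16.20 ± 0.48 (SD, n = 4) in wild type with water, 16.62 ± 0.29 with PFOA 1 mg/kg, 16.61 ± 0.09 with PFOA 3 mg/kg and 16.58 ± 0.34 with pirinixic acid (n = 4 each), and 16.65 ± 0.25 (n = 3) with methylcellulose. In null mice it averaged 15.21 ± 0.14 with water, 15.78 ± 0.17 with PFOA 1 mg/kg, 15.42 ± 0.48 with PFOA 3 mg/kg, 16.01 ± 0.20 with methylcellulose and 15.88 ± 0.22 with pirinixic acid (n = 4 each). The null-minus-wild-type difference was -0.99 ± 0.21 in water (limma adjusted p = 0.0488; 0.066 with array set as a block, 0.0749 with the replicate number as a block and 0.219 with the silent-gene index) and -0.64 ± 0.23 in methylcellulose (adjusted p = 0.249). The null signal stayed far above the median of all probes. A probe outside the deleted part would still read the remaining transcript, and the position of this probe relative to the deletion is not given in the sources used here, so Ppara does not check the genotype labels.

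Other genes do separate the genotypes, and 1 array went against its label. Cox6b2, the testis-type subunit 6b of cytochrome c oxidase, was 13.95 ± 0.51 in wild type with water and between 7.61 and 8.44 in the null group means. On the array labelled wild type, PFOA 1 mg/kg, replicate 3, Cox6b2 was 9.06, while the other 3 arrays of the group lay between 16.4 and 17. On the same array Ehhadh was 15.94 against 20.01 to 20.31, and Cyp4a14 was 11.65 against 20.21 to 20.28. That array stays in the fit under its label, so wild-type PFOA 1 mg/kg changes are given with it and checked without it.

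The arrays also fell into sets that the labels do not record. A group of 84 probes separated 16 arrays from 23 with a median difference of log2 4.37. Both sets were present in every group except wild type with pirinixic acid, whose 4 arrays were all in the larger set. A second pattern ran across arrays of all groups. The mean of 582 probes for genes silent in liver (olfactory, vomeronasal and taste receptors and keratin-associated proteins), called the silent-gene index here, ranged from 8.68 to 9.23. It correlated across the 39 arrays with the second principal component of the other 24713 probes (r = -0.94, permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted over 5 relations p = 2.5e-05). Spearman's rho was -0.857 and r without the 2 farthest arrays -0.944; that component held 11.6% of the variance. The index differed by -0.170 between wild-type PFOA 3 mg/kg and water (exact permutation p = 0.114), by -0.196 for 1 mg/kg (p = 0.0571) and by 0.154 for pirinixic acid (p = 0.143). Between null and wild type it differed by -0.218 on water (exact permutation p = 0.0857) and by 0.167 on methylcellulose (p = 0.0571). Counts with array set as a block and with the index as a covariate are given beside many of the main ones. They are not both given for null mice with PFOA 1 mg/kg, dose differences, PFOA against pirinixic acid, or where no probe changed.

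**Figure D1:**
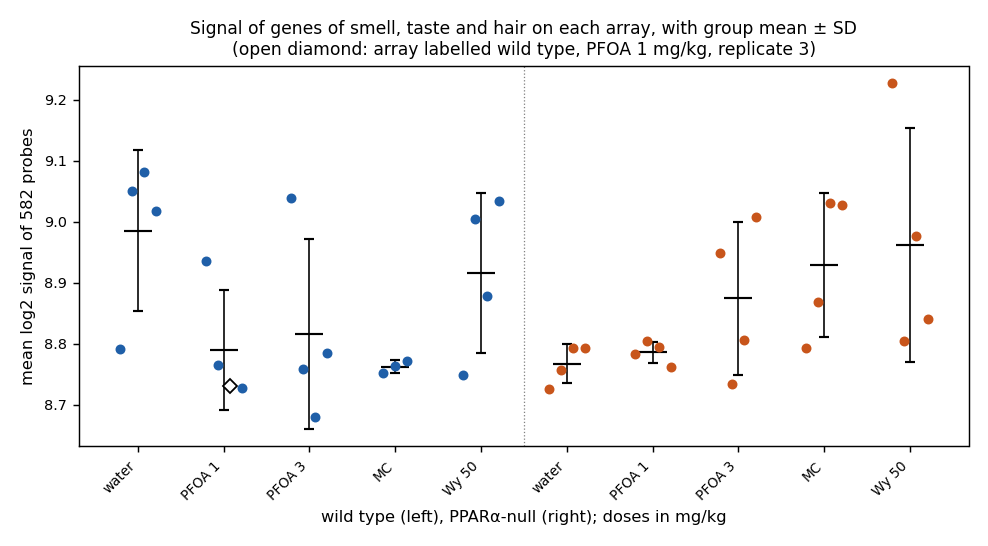
Mean log2 signal of the 582 probes for genes silent in liver (vertical axis) for each array, arranged by group on the horizontal axis. The lowest array, at 8.68, is in the wild-type PFOA 3 mg/kg group and the highest, at 9.23, in the null pirinixic acid group.

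PFOA at 3 mg/kg in wild-type mice raised genes of fatty acid uptake, activation and oxidation and lowered genes of complement and coagulation. Cyp4a31, which with Cyp4a14 belongs to the omega-hydroxylases of fatty acids, rose 240-fold (log2 7.91 ± 0.82, n = 4 against 4), and Cyp4a14 rose by log2 6.69 ± 1.65. The acyl-CoA thioesterase Acot1 rose 73.1-fold (log2 6.19 ± 0.51) and Ehhadh, a bifunctional enzyme of peroxisomal beta-oxidation, 22.1-fold (log2 4.47 ± 0.52). Cyp2c55, a cytochrome P450 induced through CAR and PXR, rose 21.7-fold (log2 4.44 ± 0.45). Hsd3b5, a steroid dehydrogenase of male liver, fell 28.8-fold (adjusted p = 2.75e-05).

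The fatty acid lists had the largest medians among the gene lists. Of 24 genes of omega-oxidation and fatty acid handling, 18 rose and none fell (21 adjusted over the list alone), with a median of log2 1.85 (camera adjusted p = 1.15e-24; adjusted p = 0.0232 with an estimated correlation). They include the fatty acid transporter Cd36 (log2 4.36 ± 0.39), the lipid-droplet coat protein Plin2 (2.75 ± 0.40), Pdk4, a kinase that holds back glucose oxidation (4.97 ± 0.91, adjusted p = 0.000579), and the hormone Fgf21 (2.89 ± 0.77, adjusted p = 0.0208). Of 25 peroxisomal genes 13 rose (16 up and 1 down adjusted over the list alone), with a median of 0.93 (adjusted p = 4.56e-12, and 0.0371 with an estimated correlation); Ech1 (2.39 ± 0.31), Acaa1a (1.55 ± 0.20) and the division factor Pex11a (2.75 ± 0.43) were among them. Of 16 mitochondrial beta-oxidation and ketogenesis genes 11 rose (12 adjusted over the list alone), with a median of 1.10 (adjusted p = 2.4e-13, and 0.0371 with an estimated correlation), among them Decr1 (2.13 ± 0.21), Cpt2 (1.35 ± 0.30) and Acadl (1.51 ± 0.26). The largest other rises were in Krt23, a keratin (63.8-fold), Mogat1, a monoacylglycerol acyltransferase (5.96 ± 0.78), Hes7, a transcriptional repressor (5.69 ± 0.66), Ston1 (5.40 ± 1.14, with another probe of the gene moving the other way), Amn, a receptor partner in endocytosis (5.29 ± 0.60), and Acot3 (5.04 ± 0.78).

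Complement and coagulation genes fell together. Of 32 measured, 23 fell and none rose (27 adjusted over the list alone), with a median of -0.76 (adjusted p = 2.29e-23, and 0.0232 with an estimated correlation). C8b fell by 1.58 (SE 0.24), C9 by -1.40 ± 0.26, fibrinogen Fgb by -0.98 ± 0.18 and Cfb by -0.82 ± 0.14. Of 24 genes of amino acid catabolism and the urea cycle 8 fell (16 adjusted over the list alone, median -0.62, adjusted p = 6.82e-10, and 0.0991 with an estimated correlation), including argininosuccinate lyase Asl (-1.14 ± 0.22) and Prodh (-1.10 ± 0.26). Of 15 acute phase genes Apcs (-1.22 ± 0.31) and Itih3 (-0.72 ± 0.20) fell (6 adjusted over the list alone, median -0.54, adjusted p = 0.000911, and 0.266 with an estimated correlation). 5 of 14 male-biased genes fell (5 adjusted over the list alone, median -0.37, adjusted p = 0.000901, and 0.227 with an estimated correlation): Hsd3b5, C8b, Susd4, Slco1a1 and Ugt2b1. Of 12 female-biased genes only Hao2, a peroxisomal 2-hydroxy acid oxidase, rose (1.83 ± 0.47; 1 adjusted over the list alone, median 0.05, adjusted p = 0.712). The largest falls also included Hsd3b4, Hsd3b2, Slco1a4, an organic anion transporter (-3.54 ± 0.61), Cyp39a1, an oxysterol hydroxylase (-2.79 ± 0.56), Ifitm3, an interferon-induced membrane protein (-2.43 ± 0.21), Cyp4f14, Lrtm1, Cd200r3 and the protease inhibitor A2m. A2m fell by 2.45 (adjusted p = 0.0403) but by 1.12 with the silent-gene index (adjusted p = 0.101), and its difference was -0.30 in the smaller array set and -4.60 in the larger.

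Genes of xenobiotic metabolism moved in part. On the CAR and PXR list 6 of 26 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.30, adjusted p = 0.00168, and 0.327 with an estimated correlation). Cyp2c55, Cyp2b10 (2.13 ± 0.58, adjusted p = 0.0234), Alas1, which makes heme (2.61 ± 0.52), and Gadd45b (3.80 ± 0.66) rose; Slco1a4, a PXR target, fell. On the NRF2 and glutathione list 5 of 22 rose (6 adjusted over the list alone, median 0.16, adjusted p = 0.00151, and 0.15 with an estimated correlation), among them Srxn1 (3.99-fold), Gstm4 (1.65 ± 0.25) and Ephx1 (0.83 ± 0.13). None of 4 AhR targets passed (none adjusted over the list alone, median -0.37, adjusted p = 0.24). Nr1i3, which encodes CAR, did not pass (0.25 ± 0.18, adjusted p = 0.506), nor did Cyp7a1 (0.28 ± 0.82, adjusted p = 0.907).

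12 of 27 proteasome subunits rose (18 adjusted over the list alone, median 0.40, adjusted p = 1.98e-11, and 0.0805 with an estimated correlation), and 7 rose with the silent-gene index; Psmb4 rose by log2 0.72 ± 0.13. Of 27 cell cycle genes 5 rose (6 adjusted over the list alone, median 0.65, adjusted p = 0.000527, and 0.22 with an estimated correlation), including Cdc20 (2.47 ± 0.50) and cyclin D1, Ccnd1 (1.30 ± 0.31). Of 22 fatty acid and triglyceride synthesis genes 7 rose and Mlxipl fell (12 and 2 adjusted over the list alone, median 0.45, adjusted p = 0.000714, and 0.227 with an estimated correlation); the desaturase Fads2 (1.33 ± 0.23) and the elongase Elovl5 (1.47 ± 0.27) lengthen and desaturate fatty acids rather than start their synthesis. On the oxidative phosphorylation list Cycs and Ndufb3 rose of 27 (2 adjusted over the list alone, median 0.18, adjusted p = 0.000376, and 0.2 with an estimated correlation). Of 14 glucose and glycogen genes 2 rose and 2 fell (2 and 6 adjusted over the list alone, median -0.53, adjusted p = 0.0352, and 0.249 with an estimated correlation and 0.0745 with the silent-gene index). The risen pair, Gpd1 and Gpd2, belongs to the glycerol phosphate shuttle.

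The remaining lists did not pass as groups. On the cholesterol list Pmvk alone rose of 15 (1.03 ± 0.31; 1 adjusted over the list alone, median 0.43, adjusted p = 0.0522, and 0.0387 with the replicate number as a block). On the bile acid list 2 of 20 rose and 4 fell (4 and 8 adjusted over the list alone, median -0.30, adjusted p = 0.0925). On the lipoprotein list the phospholipid transfer protein Pltp rose (3.61 ± 0.35) and Apom fell (-1.04 ± 0.17) of 15 (1 and 2 adjusted over the list alone, median -0.12, mean 0.06, test downward, adjusted p = 0.316). On the chaperone list Hspe1 rose and 4 of 20 fell (2 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.471), including Hspa5 (-0.75 ± 0.20). On the p53 list Fas alone rose of 11 (1.03 ± 0.25; 1 adjusted over the list alone, median -0.04, mean 0.21, test upward, adjusted p = 0.718).

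Among the cell markers, Kupffer cell genes had a median of -0.50 (adjusted p = 0.0051, and 0.573 with an estimated correlation), with Vsig4 fallen of 10 (4 adjusted over the list alone). Hepatocyte markers had a median of -0.41 (adjusted p = 0.0144, and 0.501 with an estimated correlation), with Ahsg fallen of 7 (5 adjusted over the list alone). The other marker lists did not pass: stellate cell -0.23 (adjusted p = 0.406, Dcn fallen of 10), endothelial cell -0.12 with a mean of 0.01 and a downward test (0.406; of 11 genes Lyve1 rose and Kdr and Stab2 fell), cholangiocyte 0.01 (0.519; Krt23 alone rose of 5), lymphocyte -0.27 (0.457), neutrophil -0.04 (0.695), red blood cell 0.01 with a mean of -0.02 and a downward test (0.977), pancreas acinar cell -0.25 (0.632) and adipocyte -0.18 (0.808).

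In all, 1473 probes changed, 852 up and 621 down, covering 865 named genes; 739 changed at least 2-fold. The count was 1663 with array set as a block, 262 and 1128 within the smaller and the larger set alone, and 1266 with the silent-gene index, which kept 966 of the probes. All changed probes had the same sign in both sets, which calling them on the arrays of both sets together strongly favours. The balance of rises and falls turned: 71.8% of the probes changed within the smaller set were up, and 39.7% within the larger. Leaving out 1 array gave 825 to 1943 probes; it gave 825 without treated replicate 3 and 859, 966 and 972 without water replicates 2, 3 and 4. Of the 20 genes the rule named, 18 stayed changed whichever array was left out; A2m and Cd200r3 did not.

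**Figure D2:**
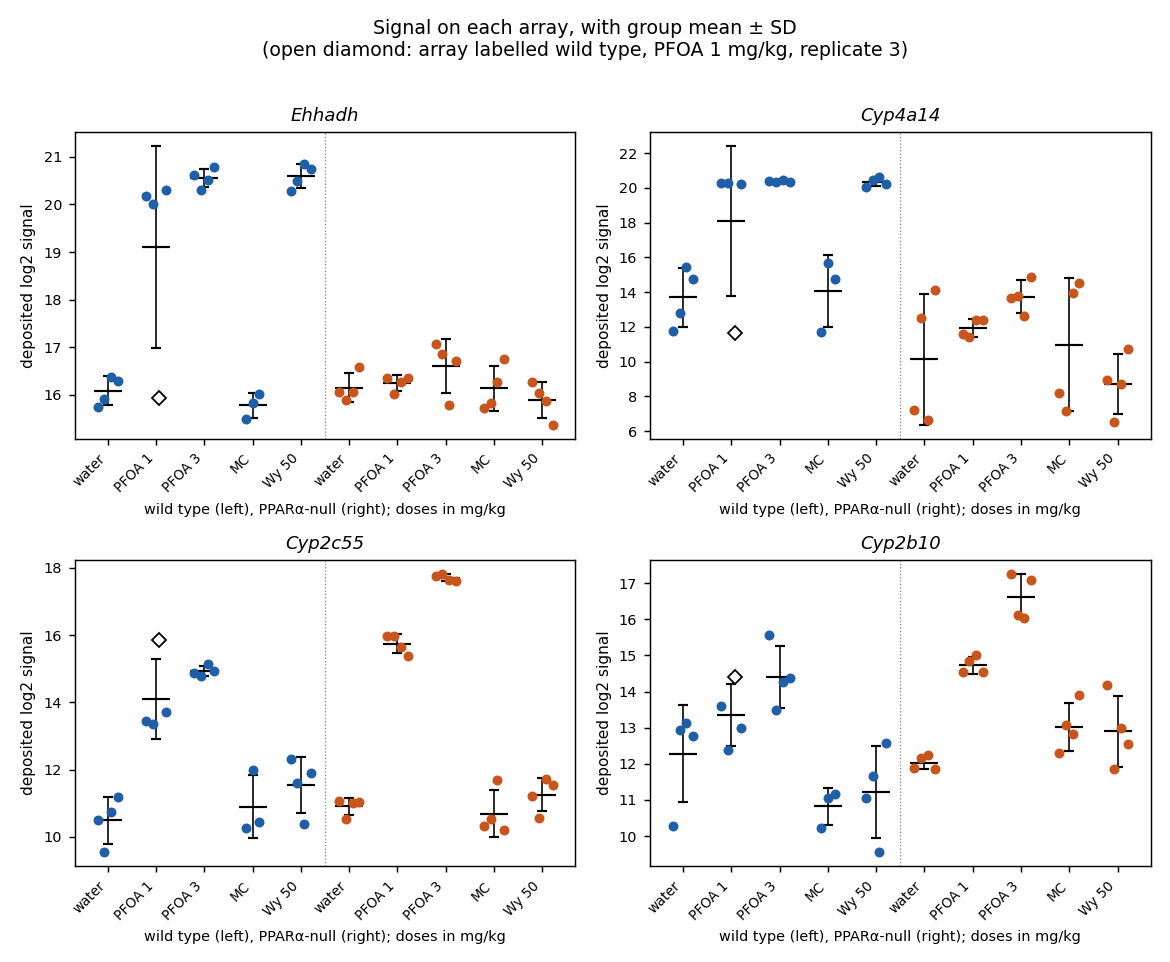
Deposited log2 signal (vertical axis) of Ehhadh, Cyp4a14, Cyp2c55 and Cyp2b10 for every array by treatment group, wild type left in blue and null right in orange, with the group mean ± SD; the open diamond is the array labelled wild type, PFOA 1 mg/kg, replicate 3. Ehhadh averaged 20.55 with PFOA 3 mg/kg and 16.09 with water in wild type, while Cyp2c55 averaged 17.70 with PFOA 3 mg/kg and 10.92 with water in null mice.

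PFOA at 1 mg/kg in wild-type mice changed 69 probes. Cyp4a31 rose 43.7-fold (log2 5.45 ± 0.82, n = 4 against 4), Acot1 28.2-fold (4.82 ± 0.51), Cyp2c55 12.2-fold (3.61 ± 0.45) and Ehhadh 8.12-fold (3.02 ± 0.52). Leaving out the array labelled replicate 3 gave 6.91 for Cyp4a31, 5.23 for Acot1, 3.01 for Cyp2c55 and 4.08 ± 0.26 for Ehhadh (adjusted p = 1.03e-11). Hes7 (4.26 ± 0.66), Krt23 (4.14 ± 0.72), Acot3 (3.83 ± 0.78), Ifi27l2b, an interferon-inducible gene (2.90 ± 0.40), Cd36 (2.31 ± 0.39), the laminin chain Lamb3 (2.18 ± 0.32) and the trehalase Treh (2.17 ± 0.34) also rose, and without that array these changes were 5.25, 5.27, 4.59, 2.93, 3.07, 2.07 and 2.50 in the same order. Few genes fell: Galnt14 (-1.11 ± 0.24), Ifitm3 (-1.08 ± 0.21), Ctsc (-1.05 ± 0.23) and Dexi (-0.94 ± 0.22) had adjusted p between 0.0107 and 0.0486, and Acot3 and all 4 of these lost the call when some single array was left out, as did Acot3, Ctsc and Dexi with the silent-gene index. Without the array labelled replicate 3 Galnt14 lost its call (-0.997 ± 0.257, adjusted p = 0.0516) and the other named genes kept theirs.

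On the fatty acid lists, 4 of 24 omega-oxidation genes rose (14 adjusted over the list alone, median 0.88, adjusted p = 3.26e-14, and 0.0805 with an estimated correlation), 4 of 25 peroxisomal genes (10 adjusted over the list alone, median 0.41, adjusted p = 3.09e-08; 0.0948) and 2 of 16 mitochondrial genes (9 adjusted over the list alone, median 0.63, adjusted p = 4.6e-09; 0.0948). Without the array labelled replicate 3, 11, 11 and 6 rose, and the p-values with an estimated correlation were 0.00501, 0.00104 and 0.00122. NRF2 genes Ephx1 (0.71 ± 0.13) and Gstt2 (1.00 ± 0.22) rose (median 0.17, adjusted p = 0.00648, and 0.207 with an estimated correlation; median 0.27 without that array), and Cyp2c55 alone rose on the CAR and PXR list (4 up and 1 down adjusted over the list alone, median 0.15, adjusted p = 0.00669; 0.382; median 0.27 without that array). Complement genes had a median of -0.29 with none fallen (adjusted p = 1.85e-09, and 0.15 with an estimated correlation, and 0.0289 without that array). The lists of cholesterol (0.36, adjusted p = 0.0111), fatty acid synthesis (0.37, 0.00219), amino acid catabolism (-0.16, 0.0133), acute phase (-0.46, 0.00275), proteasome (0.19, 5.45e-05), cell cycle (0.53, 0.000638) and oxidative phosphorylation (0.20, 0.000382) passed with no member changed, and the same lists had p between 0.2 and 0.556 with an estimated correlation. Without that array their medians were 0.39, 0.41, -0.22, -0.43, 0.26, 0.58 and 0.22, and all still passed, with p between 0.118 and 0.611 with an estimated correlation. No marker list passed, and without that array the Kupffer cell list did (-0.37 against -0.22; adjusted p = 0.00407, and 0.539 with an estimated correlation). Cyp4a14 (4.40 ± 1.65, adjusted p = 0.318; 6.55 ± 1.49, 0.0189 without that array), Pdk4 (2.25 ± 0.91, 0.358), Cyp2b10 (1.06 ± 0.58, 0.509), Fgf21 (0.56 ± 0.77, 0.843), Cyp7a1 (0.53 ± 0.82, 0.861) and Nr1i3 (0.36, 0.463) did not pass. Without that array Pdk4 was at 2.39 (adjusted p = 0.364), Cyp2b10 at 0.71 (0.756), Fgf21 at 1.91 ± 0.55 (0.102), Cyp7a1 at 1.13 ± 0.85 (0.703) and Nr1i3 at 0.35 (0.571), which did not pass either.

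The count was 69 probes, 61 up and 8 down, in 43 named genes. It was 67 with array set as a block, 29 within the smaller and 1 within the larger array set, 51 with the silent-gene index and 249 (209 up, 40 down) without the array labelled replicate 3. Other single arrays left 32 and 39 (treated replicates 2 and 4) and 40, 41 and 43 (water replicates 2 to 4). Genes changed only without it, read after the values were seen, include Osbpl3 (3.33 ± 0.55) and Hsd3b2 (-1.85 ± 0.34).

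The doses differed at few probes when compared directly. Between 3 and 1 mg/kg in wild type 7 probes differed (4 higher, 3 lower at 3 mg/kg; 1898 at unadjusted p under 0.05). Amn was higher by 3.21 ± 0.60, the pancreatic lipase relative Pnliprp1 by 3.06 ± 0.59 and the fatty acid transporter Slc27a1 by 2.33 ± 0.38, and Ifitm3 was lower (-1.35 ± 0.21). Of these only Ifitm3 stayed without the array labelled replicate 3 (-1.03, adjusted p = 0.0235), where the count was 2. With the replicate number as a block the count was 4, and Amn (adjusted p = 0.0557) and Pnliprp1 (0.0641) lost their calls. Ehhadh differed by 1.45 ± 0.52 (adjusted p = 0.439), and by 0.39 ± 0.26 (adjusted p = 1) without the array labelled replicate 3, so most of that difference came from this array.

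Pirinixic acid in wild-type mice raised genes of fatty acid oxidation and of cholesterol synthesis. The omega-oxidation list also passed with an estimated correlation (camera adjusted p = 0.0371), and the cholesterol list did not (0.154). Cyp4a31 rose 104-fold (log2 6.71 ± 0.88, n = 4 against 3), Ehhadh 28.0-fold (4.81 ± 0.56), Cd36 21.6-fold (4.43 ± 0.42) and Fabp4, a fatty acid binding protein best known from adipocytes, by log2 4.39 ± 0.32. Obp2a, a lipocalin, fell by 5.33 (SE 0.97), Hsd3b5 by 4.49 (SE 0.75) and Slco1a1, a transporter of male liver, by 2.79 (SE 0.35). Cyp2c55 (0.66 ± 0.48, adjusted p = 0.47) and Cyp2b10 (0.39 ± 0.63, adjusted p = 0.782) did not pass.

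14 of 24 omega-oxidation genes rose (18 adjusted over the list alone, median 1.66, adjusted p = 6.34e-18, and 0.0371 with an estimated correlation). 8 of 25 peroxisomal genes rose (13 adjusted over the list alone, median 0.66, adjusted p = 1.04e-07; 0.0991), with Ech1 at 1.71 ± 0.33, and 6 of 16 mitochondrial genes (9 adjusted over the list alone, median 1.04, adjusted p = 1.55e-07; 0.134), with Acadl at 1.61 ± 0.28. 9 of 15 cholesterol genes rose (13 adjusted over the list alone, median 1.18, adjusted p = 8.53e-11; 0.154), including Hmgcs1 (2.64 ± 0.55), Idi1 (1.64 ± 0.34) and Cyp51 (1.48 ± 0.35). On the fatty acid synthesis list 8 of 22 rose and Mlxipl fell (8 and 2 adjusted over the list alone, median 0.52, adjusted p = 4.77e-05; 0.165), among them Elovl5 (4.01-fold) and the desaturase Scd1 (3.15 ± 0.84). 7 of 27 cell cycle genes rose and Tk1 fell (7 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.000172; 0.2), including Mcm5 (2.04 ± 0.38) and Birc5 (3.15 ± 0.72). Proteasome (median 0.25, 4 of 27 rose, 5 adjusted over the list alone, adjusted p = 1.72e-05; 0.238) and oxidative phosphorylation (0.17, 3 of 27 rose, adjusted p = 0.000175; 0.191) passed as well.

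Complement and coagulation fell in 19 of 32 genes (25 adjusted over the list alone, median -0.68, adjusted p = 5.04e-17, and 0.0371 with an estimated correlation), with C8b at -2.39 ± 0.26 and C8a at -1.83 ± 0.27. 6 of 14 male-biased genes fell (7 adjusted over the list alone, median -1.10, adjusted p = 2.62e-06; 0.0982), with Ugt2b1 at -1.96 ± 0.29. 5 of 14 glucose genes fell (2 up and 7 down adjusted over the list alone, median -0.80, adjusted p = 0.0146; 0.2): Fbp1, Pklr, Slc37a4, Pck1 and Pygl. Otc (-1.27 ± 0.27) and Asl (-1.12 ± 0.24) fell on the amino acid list (2 adjusted over the list alone, median -0.35, adjusted p = 0.00728; 0.435), and Itih3 on the acute phase list (2 adjusted over the list alone, median -0.61, adjusted p = 0.0233; 0.42, and 0.0747 with the silent-gene index). Not passing as groups were CAR and PXR (3 up and 4 down of 26, median -0.30, adjusted p = 0.427), NRF2 (2 and 2 of 22, 0.06, 0.24), AhR (Cyp1a2 fell, 0.10, 0.712), bile acid (2 and 3 of 20, -0.36, 0.336), lipoproteins (Pltp rose, Apom and Apoa4 fell, -0.26, 0.0991), chaperones (2 and 1 of 20, -0.13, 0.82), p53 (Fas rose, 0.29, 0.204) and female-biased genes (0.04, 0.734), where Hao2 rose by 4.07 ± 0.50.

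Markers of Kupffer cells (median -0.62, 4 of 10 fell, 6 adjusted over the list alone, adjusted p = 0.00499, and 0.573 with an estimated correlation), endothelial cells (-0.54, 6 of 11 fell, 1 up and 7 down adjusted over the list alone; 0.0053; 0.501) and hepatocytes (-0.39, 2 of 7 fell, 4 adjusted over the list alone; 0.0246; 0.501) shifted down. Clec4f (-0.97 ± 0.21) and Vsig4 (-0.79 ± 0.19) were among the Kupffer genes that fell. The largest other rises were in Ston1 (6.69 ± 1.23), Cyp4a14 (6.29 ± 1.78, adjusted p = 0.0304; 0.087 with the silent-gene index), Amn, Mogat1, Hes7, Lamb3 (4.83 ± 0.34) and Pdk4 (3.69 ± 0.98). Much of the Pdk4 rise came from treated replicate 3, at 19.5. The other treated arrays lay between 12.1 and 14.3, and the vehicle arrays averaged 10.91 ± 0.71. Hsd3b4, Noct, a deadenylase with a daily rhythm (-2.94 ± 0.81), Cd200r3, Mpp4, Ifitm3 (-2.47 ± 0.23) and Hsd3b2 fell.

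In all 1542 probes changed, 708 up and 834 down, in 883 named genes. The count was 1575 with array set as a block, 249 within the larger array set, the only set with treated arrays, and 1353 with the silent-gene index, which kept 1071. The balance of rises and falls was not stable: 720 rose and 633 fell with the index, and 64.3% rose within the larger array set, 87.1% with only the groups compared and 52.2% without vehicle replicate 1. It was 2399 and 859 without treated replicates 1 and 3, and 835, 876 and 797 without vehicle replicates 1 to 3. Of the 20 genes named, Cyp4a14 and Noct lost the call when some single array was left out. Noct also lost it with the clock index and array set as a block together (limma adjusted p = 0.109), and kept it with array set alone as a block. With only 3 vehicle arrays this comparison rests more on each of them than the others do.

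**Figure D3:**
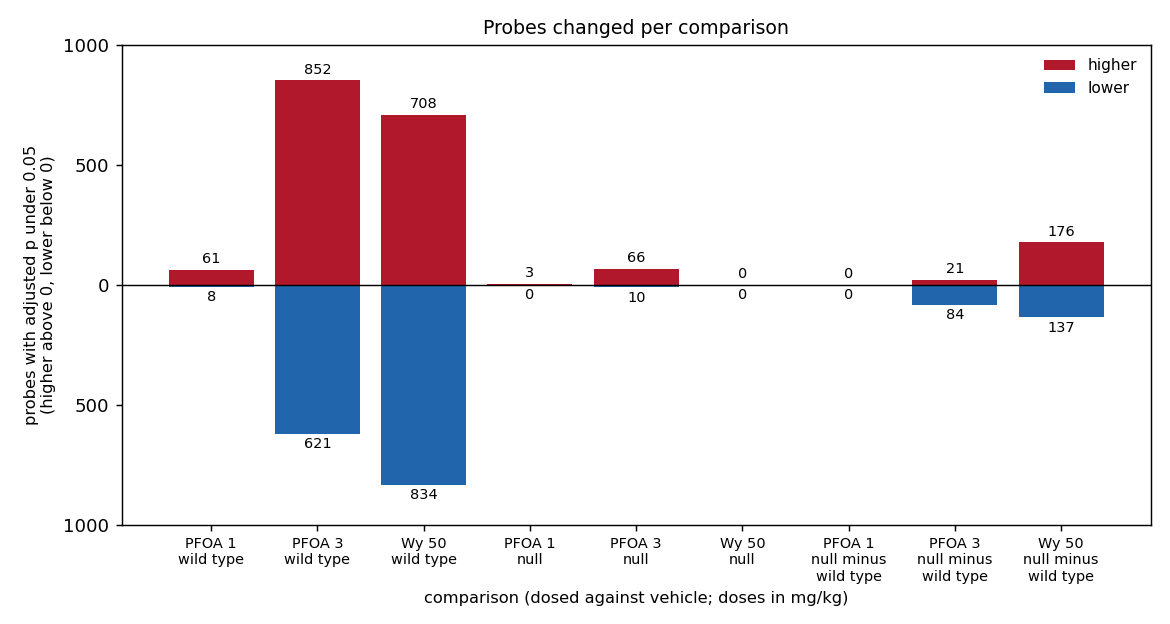
Number of probes with an adjusted p under 0.05 (vertical axis), higher and lower as separate bars, for the 6 treated groups against their vehicles and for the 3 null-minus-wild-type differences. PFOA 3 mg/kg changed 1473 probes in wild type and 76 in null mice, and pirinixic acid changed 1542 and 0.

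PFOA 3 mg/kg and pirinixic acid shared many changes in wild type, although the doses, vehicles and control groups differ. 526 probes changed in the same direction with both, 316 up and 210 down, and none in opposite directions; independent lists of these sizes would share 23.8 up and 20.5 down. Of the probes that PFOA changed, 89.4% had the same sign with pirinixic acid. The median over these probes of the pirinixic acid change divided by the PFOA change was 0.627. Picking probes by their PFOA change pulls this ratio down. Across all tested probes, which are not independent replicates, r was 0.254. The shared count was 562 with array set as a block and 579 with the silent-gene index. Tested directly, the responses differed at 3 probes, 1 higher and 2 lower with PFOA (3392 at unadjusted p under 0.05). Cyp2c55 responded more to PFOA by log2 3.78 ± 0.66 (adjusted p = 0.0268; 0.0598 with the replicate number as a block and 0.106 with the silent-gene index, and lost when some single array was left out), and Fabp4 responded more to pirinixic acid, with a difference of -3.44 ± 0.43 (adjusted p = 0.00014). The differences for Ehhadh (-0.34 ± 0.76, adjusted p = 0.89), Cyp4a14 (0.40 ± 2.43, 0.964), Pdk4 (1.28 ± 1.33, 0.728) and Cyp2b10 (1.74 ± 0.85, 0.372) did not pass. The count was 1 with the replicate number as a block and 609 within the larger array set alone.

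PFOA at 3 mg/kg in PPARα-null mice changed 76 probes, and genes of the CAR and PXR list rose (5 of 26, camera adjusted p = 6.34e-18). Cyp2c55 rose 110-fold (log2 6.79 ± 0.45, n = 4 against 4) and Cyp2b10, the usual marker of CAR activation, 24.2-fold (4.60 ± 0.58). S100a8, a calcium-binding protein of neutrophils, rose 174-fold (7.44 ± 0.70), and the collagen chain Col1a1 8.59-fold (3.10 ± 0.38). Cyp4a31 rose 18.6-fold (4.22 ± 0.82, adjusted p = 0.00944). Ehhadh (0.45 ± 0.52, adjusted p = 0.876), Cyp4a14 (3.61 ± 1.65, 0.559), Pdk4 (-0.75, 0.885) and Fgf21 (-0.45, 0.923) did not pass.

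5 of 26 CAR and PXR genes rose and none fell (9 adjusted over the list alone, median 0.58, adjusted p = 6.34e-18, and 0.0232 with an estimated correlation): Cyp2c55, Cyp2b10, Ces2a (1.67 ± 0.19), Ugt2b34 (0.93 ± 0.14) and Cyp2b13 (2.76 ± 0.55). 3 of 22 NRF2 genes rose (5 adjusted over the list alone, median 0.16, adjusted p = 1.05e-05; 0.0371): Ephx1 (0.87 ± 0.13), Gstm4 (1.31 ± 0.25) and Gstm2 (1.35 ± 0.26). The cell cycle list had a median of 0.59 (adjusted p = 1.23e-09; 0.0371), with the replication helicase subunit Mcm6 risen (2.54 ± 0.52; 8 adjusted over the list alone). Single members rose on the peroxisomal list (Acaa1b 1.60 ± 0.27; median 0.06, adjusted p = 0.0148, and 0.42 with an estimated correlation) and the mitochondrial list (Acadl 1.32 ± 0.26; 0.17, 0.00728; 0.399), and Creb3l3 (1.05 ± 0.19) and Cyp4a31 on the omega-oxidation list (0.28, 9.99e-06; 0.277). Mat1a fell on the amino acid list (median -0.37, adjusted p = 5.26e-07; 0.2). Cholesterol (0.22, adjusted p = 0.00685; 0.537), fatty acid synthesis (0.18, 0.0121; 0.367), complement (-0.14, 0.00567; 0.464) and proteasome (0.08, 0.00463; 0.419) passed with no member changed. The female-biased list passed narrowly (0.44, adjusted p = 0.0493; 0.341, and 0.065 with array set as a block) on Cyp2b13 alone. No marker list passed: on the neutrophil list S100a8 alone rose (median -0.28, mean 1.36, test upward, adjusted p = 0.161), with S100a9 at -0.28, and on the stellate list Col1a1 alone (median -0.40, adjusted p = 0.456).

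76 probes changed, 66 up and 10 down, in 44 named genes. The count was 74 with array set as a block, 22 and 4 within the smaller and the larger set, and 88 with the silent-gene index. It fell to 43 and 45 without water replicates 1 and 3. Ifi27l2b (2.73 ± 0.40), Cnmd, a cartilage glycoprotein (2.43 ± 0.32), and the carboxylesterase Ces1g (2.28 ± 0.22) rose. Syt3 (-1.47 ± 0.30), Svil (with another probe moving the other way), Itih3, Sult2a8, Mat1a and Nfia fell. All 6 that fell, and Cyp4a31, Cyp2b13 and Mcm6, lost the call when some single array was left out.

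At 1 mg/kg in null mice 3 probes changed, all up: Cyp2c55 28.4-fold (4.83 ± 0.45), Cnmd 3.67-fold (1.88 ± 0.32) and Ces1g 2.87-fold (1.52 ± 0.22). An unadjusted limma p under 0.05 was found at 1003 probes, fewer than 0.05 of the tested probes. Cyp2b10 was 2.70 ± 0.58 with adjusted p = 0.182, and 2.60 with adjusted p = 0.00432 with the silent-gene index. The CAR and PXR list passed (Cyp2c55 risen, 6 adjusted over the list alone, median 0.28, adjusted p = 2.4e-13, and 0.0371 with an estimated correlation). Mitochondrial beta-oxidation (0.30, adjusted p = 0.00455; 0.372), omega-oxidation (0.27, 0.000241; 0.367), cholesterol (0.47, 1.55e-07; 0.227), amino acid catabolism (-0.29, 5.45e-05; 0.266), complement (-0.10, 0.0329; 0.584) and cell cycle (0.31, 0.00433; 0.299) passed with no member changed. The cholesterol median was -0.10 in the smaller array set and 1.5 in the larger. Between 3 and 1 mg/kg, S100a8 was higher by 6.45 ± 0.70 (87.5-fold) and Col1a1 by 2.23 ± 0.38 at the higher dose; these were the only 2 probes to differ, and Cyp2c55 (1.96 ± 0.45, adjusted p = 0.329) did not. Col1a1 in this comparison, and Cnmd at 1 mg/kg, lost the call when some single array was left out. They also lost it with the clock index and array set as a block together, and kept it with array set alone as a block.

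With pirinixic acid in null mice 0 probes changed by limma. An unadjusted p under 0.05 was found at 691, fewer than in the other treated groups and fewer than 0.05 of the tested probes. Ehhadh was at -0.25 ± 0.52, Cyp4a14 at -2.24 ± 1.65 and Cyp2c55 at 0.56 ± 0.45, each with adjusted p = 1. Cholesterol (median 0.48, adjusted p = 1.14e-05, and 0.313 with an estimated correlation; -0.09 and 0.65 in the smaller and larger array sets), acute phase (-0.15, 0.00728; 0.367), proteasome (0.10, 0.0336; 0.556) and Kupffer cell markers (0.39, 0.000153; 0.501) passed with no member changed. The peroxisomal list (0.05, adjusted p = 0.723) and the omega-oxidation list (0.08, mean -0.03, adjusted p = 0.948) did not pass. Compared with pirinixic acid, PFOA 3 mg/kg gave a higher response at 12 probes in null mice and a lower one at none. These include Cyp2c55 (6.22 ± 0.63), S100a8 (5.87 ± 0.99), Cyp2b10 (4.73 ± 0.82), Col1a1 (3.17 ± 0.54) and the protease Prss8 (2.49 ± 0.50, limma adjusted p = 0.0467, and 0.0548 without the array labelled replicate 3). The count of 12 was 20 with the silent-gene index, 1 within each array set and 7 without null methylcellulose replicate 3.

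PFOA 3 mg/kg changed 34 probes alike in both genotypes, 28 up and 6 down, where independent lists would share 2.22 and 0.246; the count was 34 with array set as a block and 44 with the silent-gene index. These probes were read as a group after the values were seen. Cyp2c55 (4.44 in wild type, 6.79 in null), Cyp2b10 (2.13 and 4.60), Ces1g (1.19 and 2.28), Gstm4 (1.65 and 1.31) and Ephx1 (0.83 and 0.87) belong to xenobiotic metabolism, and Cyp4a31 (7.91 and 4.22), Acadl (1.51 and 1.32) and Acaa1b (1.43 and 1.60) to fatty acid oxidation. Itih3 (-0.72 and -0.95) and Mat1a (-0.62 and -0.81) fell in both. Across all tested probes the responses of the genotypes had r = 0.134, and 72.9% of the probes changed in wild type had the same sign in null.

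**Figure D4:**
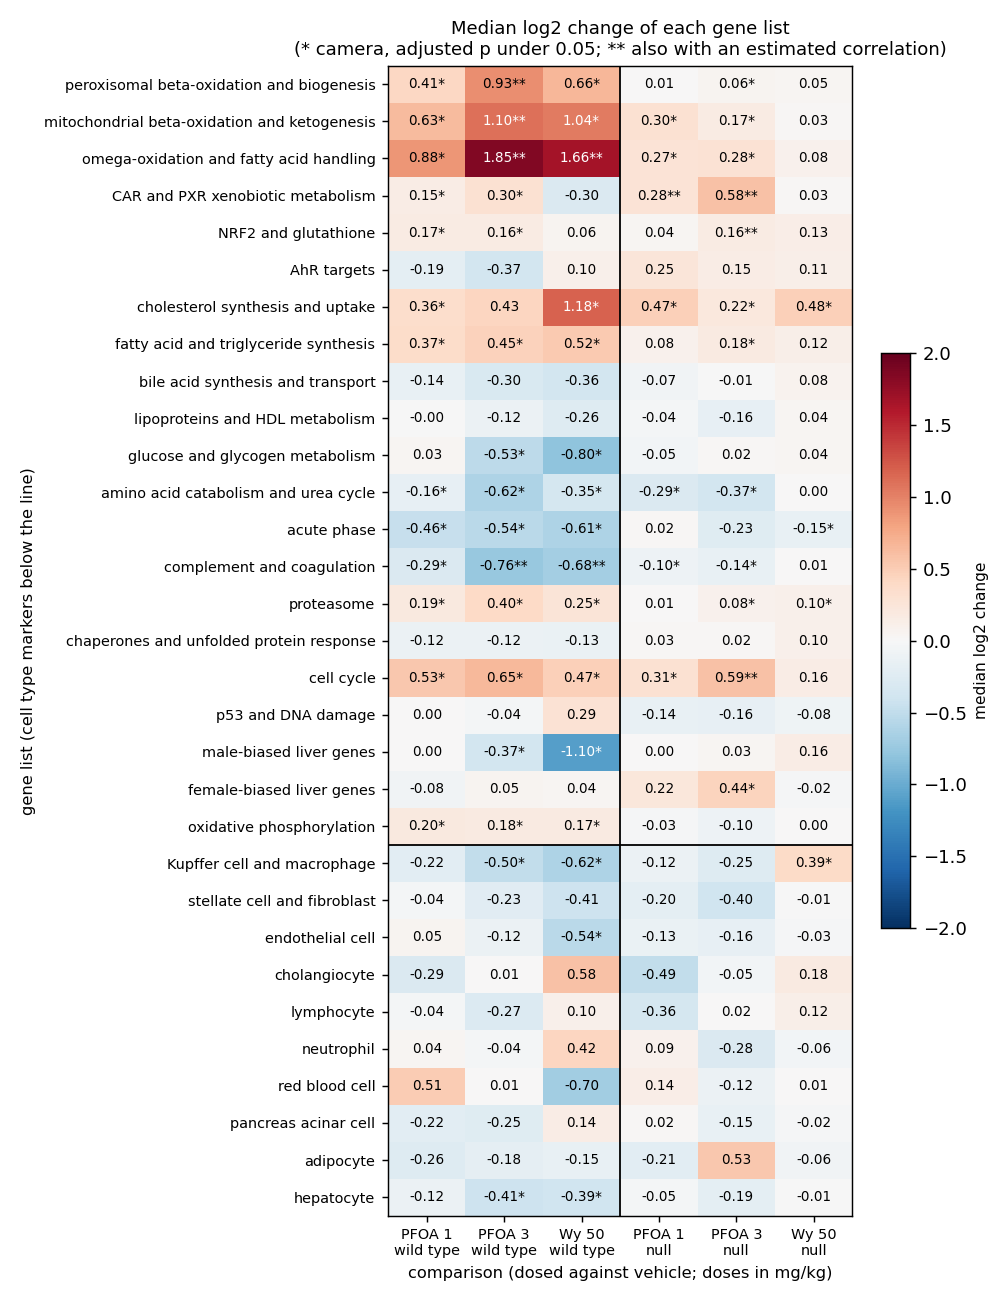
Median log2 change of each gene list and, below the line, each marker list (vertical axis) in the 6 treated groups (horizontal axis), as colour; * marks an adjusted p under 0.05 with camera and ** also with an estimated correlation. Omega-oxidation stands at 1.85 and 1.66 in wild type with PFOA 3 mg/kg and pirinixic acid and at 0.28 and 0.08 in null mice.

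Tested as a difference, the null response to PFOA 3 mg/kg was lower than the wild-type response at 84 probes and higher at 21. Leaving out 1 array at a time gave 42 to 145 probes instead of 105. Mogat1 (-6.0 ± 1.1), Pdk4 (-5.72 ± 1.28), Acot3 (-5.64 ± 1.10), Hes7 (-5.60 ± 0.93), Krt23 (-4.95 ± 1.02) and Ehhadh (-4.01 ± 0.73, adjusted p = 0.00691) responded less in null mice. S100a8 (7.48 ± 0.99), Hsd3b5 (4.32 ± 0.98), Cnmd (2.37 ± 0.45), Col1a1 (2.36 ± 0.54) and Ifitm3 (2.0 ± 0.30) responded more, or fell less. 6 of 24 omega-oxidation genes, 5 of 25 peroxisomal and 2 of 16 mitochondrial genes responded less (medians -1.59, -0.66 and -0.78, camera adjusted p = 4.66e-14, 2.48e-07 and 6.52e-08). These counts were 3, 1 and 1 with the silent-gene index, and 11, 8 and 3 without the array labelled replicate 3. Complement had a median of 0.64 (adjusted p = 3.88e-15; no member past the test over all probes, 15 adjusted over the list alone). With an estimated correlation these 4 lists had p = 0.133, and without the array labelled replicate 3 p was 0.0149, 0.00868, 0.0137 and 0.0155. The CAR and PXR list had a median of 0.37 (adjusted p = 0.00234; 0.298 with an estimated correlation and 0.0628 with the silent-gene index), with Ces2a higher in null (1.74 ± 0.27, adjusted p = 0.000816). The larger responses of Cyp2c55 (2.34 ± 0.63, adjusted p = 0.103) and Cyp2b10 (2.46 ± 0.82, 0.224) in null mice did not pass, nor did Cyp4a14 (-3.08 ± 2.34, 0.653) and Fgf21 (-3.34 ± 1.09, 0.213). Leaving out the array labelled replicate 3, which is in none of these groups and so changes only the errors, gave adjusted p = 0.0211 for Cyp2c55, 0.186 for Cyp2b10, 0.568 for Cyp4a14 and 0.0145 for Fgf21. The count of 105 was 115 with array set as a block, 17 and 0 within the sets, and 59 with the silent-gene index, where Hsd3b5, Col1a1, Pdk4 and Acot3 lost the call, as Hsd3b5, Col1a1, Pdk4 and Krt23 did when some single array was left out; it was 178 without the array labelled replicate 3.

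For pirinixic acid the genotypes differed at 313 probes, 176 higher and 137 lower in null. Ston1 (-7.14 ± 1.68), Cyp4a31 (-6.46 ± 1.21), Amn (-5.24 ± 0.88), Mogat1 (-5.21 ± 1.15) and Ehhadh (-5.06 ± 0.76) responded less in null mice. Obp2a (6.49 ± 1.32), Hsd3b5 (4.87 ± 1.02), Hsd3b4 (4.54 ± 1.02), Cd200r3 (3.98 ± 0.84) and Slco1a1 (3.16 ± 0.48) did not fall as in wild type. 7 of 24 omega-oxidation genes responded less (median -1.54, adjusted p = 3.88e-15, and 0.133 with an estimated correlation), while 7 of 32 complement genes (0.58, 2.55e-12; 0.133) and 6 of 14 male-biased genes (1.21, 6.44e-06; 0.133) were higher. Kupffer markers had a median of 1.02 (adjusted p = 2.01e-05; 0.394), with Vsig4 and C1qb higher. The count was 323 with array set as a block, 588 with the replicate number as a block, 2 within the larger set, and 444 with the silent-gene index. The balance turned to 206 higher and 238 lower with the index, to 30.2% higher with only the groups compared and to 46.7% without wild-type methylcellulose replicate 1. Hsd3b5, Hsd3b4, Ston1 and Mogat1 lost the call when some single array was left out. For PFOA 1 mg/kg 0 probes differed by limma (1274 at unadjusted p under 0.05, close to 0.05 of the tested probes). Without the array labelled replicate 3 it was 41 (2 higher, 39 lower in null), among them Ehhadh (-2.92 ± 0.73, adjusted p = 0.509, against -3.98 ± 0.36, 6.26e-08 without it). The omega-oxidation list had a median difference of -0.56 (adjusted p = 6.04e-06, and 0.241 with an estimated correlation and 0.0286 without that array).

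Without treatment, null mice on water differed from wild type at 32 probes, 14 higher and 18 lower. Sult1e1, an estrogen sulfotransferase, was 56.0-fold higher in null (log2 5.81 ± 0.97), and Serpinb1a, an inhibitor of neutrophil proteases, 15.5-fold (3.96 ± 0.64); Smpd3 (3.04 ± 0.50), Lrtm1 (2.49 ± 0.51) and Tafa2 (2.04 ± 0.38) were also higher. Cox6b2 was lower by -5.51 ± 0.93, Slc25a20, the mitochondrial acylcarnitine carrier, by -1.84 ± 0.39, Eci2 by -1.42 ± 0.30 and Acadl by -1.25 ± 0.26. Only Serpinb1a kept its call whichever array was left out. With the silent-gene index none of the 32 kept it and 1 other passed. The count was 24 with array set as a block and 7 and 2 within the sets, and 60.8% were higher without the dimmer probes. On methylcellulose 47 probes differed, 9 higher and 38 lower, 54 with array set as a block, 0 within either set and 19 with the index. Cox6b2 (-6.69 ± 1.00), Plin5, a lipid-droplet protein of oxidative tissues (-3.36 ± 0.59), Mfsd2a (-3.42 ± 0.75), Cdpf1 and Rab30 were lower, and Sult1e1 (4.98 ± 1.04), Lrtm1 (2.75 ± 0.55), Tafa2 (2.50 ± 0.41) and Dcaf4 were higher. All of these but Cox6b2 lost the call when some single array was left out, and Sult1e1, Lrtm1, Mfsd2a, Cdpf1 and Rab30 lost it with the index. Fgf21 (-2.33 ± 0.77, adjusted p = 0.369 on water; -3.30 ± 0.83, 0.0919 on methylcellulose) did not pass.

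Methylcellulose against water gave 0 probes by adjusted limma test in wild type (2191 at unadjusted p under 0.05) and 0 in null mice (2931). Both unadjusted counts are over 0.05 of the tested probes, so a vehicle difference is not excluded. The larger array set alone gave 8 in null mice.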

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

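The tests of the array labelled wild type, PFOA 1 mg/kg, replicate 3, of the silent-gene index, of array set and group means for the clock genes, and the counts of splits with the index, were chosen only after the result was seen; the other counts of splits and the test of clock genes not yet looked at were set before.

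In 9 of 108 tests of a group of 4 arrays, over the genes always reported, the number of missing values, the clock index and the silent-gene index, 1 array lay so far from the others that its gap over the group's range passed Dixon's 95% critical value; chance passes about 1 in 20 groups, or 5.4 of these. All 9 were for genes, and 5 of the 9 were the array labelled wild type, PFOA 1 mg/kg, replicate 3: Ehhadh 0.931, Cyp4a14 0.992, Cyp2c55 0.852, Cyp7a1 0.839 and Fgf21 0.874. The others were Ppara in wild type with pirinixic acid replicate 4 (0.909), Cyp2b10 in wild type with water replicate 1 (0.877), Cyp2c55 in null with water replicate 2 (0.855) and Nr1i3 in null with PFOA 1 mg/kg replicate 4 (0.943).

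The array labelled wild type, PFOA 1 mg/kg, replicate 3 had 86.4% of 44 probes that separate the genotypes nearer to the null mean, within the 75 to 100% of the 20 arrays labelled null and far from the 0 to 9.09% of the 18 other arrays labelled wild type. Over 73 probes that PFOA raises in null mice it stood 48.5% of the way from null with water to null with PFOA 3 mg/kg, where undosed null arrays stood at -5.84 to 14.0% and wild-type arrays with water at 13.3 to 28.7%. This argues against a mouse that was not dosed. It does not tell the genotypes apart, since null arrays with PFOA 1 mg/kg stood at 47.4 to 53.7% and the other wild-type arrays with that dose at 44.5 to 63.0%. A swap with another array of this series would need a null-labelled array on the wild-type side, and 0 were found. RNA from a dosed PPARα-null mouse is the explanation left open, as a wrong label or an exchange with a sample outside the series; wild-type mice differ among themselves in ways that were not tested.

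The silent-gene index followed the second component of the other probes (r = -0.94; -0.927 with group means removed), which fits a technical signal level that differs between arrays. Array set explained 0.765% of its variance within groups, and group means 37.9% of its variance, which argues against set or treatment as the whole cause. What sets the level may lie in hybridisation, labelling or RNA, and no test here separates these. No biological explanation other than the study's groups was tested.

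Genes of the daily clock varied between arrays: Arntl ranged 89.5-fold, Dbp 92.1-fold and Usp2 68.2-fold over the arrays of all groups. These ranges include differences between groups, and these genes had been looked at before the list was made. Genes not looked at before ranged from 3.87-fold (Nr1d1) to 18.9-fold (Per1). For clock genes not looked at before, the evening and morning arms had r = -0.364 after removal of group means and array set (permutation p = 0.0234, adjusted over 5 relations p = 0.039; Spearman's rho = -0.351, p = 0.0298, adjusted p = 0.0497). It was -0.259 without the 2 farthest arrays, so that it rests partly on them, and -0.456 (permutation p = 0.0756) and -0.311 (p = 0.149) within the array sets of 16 and 23. Array set explained 5.95% of the clock index within groups and group means 35.1%, which argues against array set or treatment as the whole cause. The array sets mix replicate numbers, and a batch or collection round that follows the replicate number was not tested. The time of tissue collection cannot be told apart from other sources of this spread, because the labels give no times and r fell between the values set in advance for and against it.

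The responses of the genotypes differed when the difference itself was tested, at 105 probes for PFOA 3 mg/kg and 313 for pirinixic acid. For PFOA 3 mg/kg the null-minus-wild-type differences were 7.48 for S100a8, 4.32 for Hsd3b5, 2.37 for Cnmd, 2.36 for Col1a1, 2.0 for Ifitm3, -6.0 for Mogat1, -5.72 for Pdk4, -5.64 for Acot3, -5.60 for Hes7, -4.95 for Krt23 and -4.01 for Ehhadh. For pirinixic acid they were 6.49 for Obp2a, 4.87 for Hsd3b5, 4.54 for Hsd3b4, 3.98 for Cd200r3, 3.16 for Slco1a1, -7.14 for Ston1, -6.46 for Cyp4a31, -5.24 for Amn, -5.21 for Mogat1 and -5.06 for Ehhadh.

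Probes with missing values, not used in the main counts, also carried signal. With at least 2 values required in every group, 7613 more probes were tested, and of these 1 changed in wild type with PFOA 1 mg/kg, 45 with PFOA 3 mg/kg and 47 with pirinixic acid, and 1 in null mice with PFOA 3 mg/kg.

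Other splits of the same arrays into groups of the same sizes were counted, the real one included. The shares of splits were not adjusted for the number of results, and 1 of 35 is the smallest that 35 splits can give. For the genotype differences and for PFOA against pirinixic acid, the splits exchanged arrays over all the groups that enter. Such splits carry effects of genotype or compound into the difference, so a low share there allows no conclusion on chance. The limit set in advance for excluding chance was that under 0.05 of the splits gave as many probes. This held for null mice with PFOA 1 mg/kg (1 of 35 splits; 3 probes, highest other 1) and 3 mg/kg (1 of 35; 76, highest other 1), null against wild type on water (1 of 35; 32, highest other 1) and on methylcellulose (1 of 35; 47, highest other 6), and PFOA against pirinixic acid in null mice (1 of 100; 12, highest other 3). It also held for the shared counts of PFOA and pirinixic acid in wild type (1 of 100; 526, highest other 1) and of both genotypes (1 of 100; 34, highest other 0), and for the genotype differences in the response to PFOA 3 mg/kg (3 of 100; 105, highest other 1197) and pirinixic acid (2 of 100; 313, highest other 1074).

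Chance could not be excluded in this way for wild type with PFOA 1 mg/kg (2 of 35; 69, highest other 98), PFOA 3 mg/kg (2 of 35; 1473, highest other 1665) and pirinixic acid (2 of 35; 1542, highest other 2120), nor for the dose differences in wild type (2 of 35; 7, highest other 29) and null mice (2 of 35; 2, highest other 3), or PFOA against pirinixic acid in wild type (10 of 100; 3, highest other 1595). The counts of 0 were reached by every split: null mice with pirinixic acid (35 of 35, highest other 2), the genotype difference for PFOA 1 mg/kg (100 of 100, highest other 309), the vehicles in wild type (35 of 35, highest other 3) and null (35 of 35, highest other 1), and the shared count in null mice (100 of 100, highest other 0). The split with 98 exchanged replicate 1 of water with replicate 3 of PFOA 1 mg/kg, the array that went against its label. It kept the other PFOA 1 mg/kg arrays together, and with the silent-gene index the same split was the one with 84. The split with 1665 exchanged replicate 1 of water with replicate 1 of PFOA 3 mg/kg, and the split with 2120 put replicate 1 of pirinixic acid with the vehicle arrays. Splits that call several times the real count, as for the genotype differences and for PFOA against pirinixic acid, point to a structure of the samples. The treatments may be part of that structure, though the sides were not purely of treated arrays. The split with 1074 put replicates 1, 2 and 4 of wild type with pirinixic acid in the same group as wild-type methylcellulose replicate 2. That with 1595 grouped wild-type PFOA 3 mg/kg replicates 2 and 3 with pirinixic acid replicate 1 and water replicate 1. The split with 1197 grouped null PFOA 3 mg/kg replicate 1 with water arrays of both genotypes, and what it follows was not tested. No test separates the treatments from a structure beyond the groups. Splits that follow array set gave 0 probes where they could be made. This does not show that array set has no effect, since 84 probes separate the sets by a median of log2 4.37. The fit takes its errors from all groups, most of which mix the sets, and this widens the errors at such probes. With the silent-gene index as a covariate the real split was the only one of 35 as large for wild type with PFOA 3 mg/kg (1266, highest other 1) and pirinixic acid (1353, highest other 834) and for the wild-type doses (11, highest other 5), and of 100 for the genotype differences (59, highest other 55; 444, highest other 398), but 3 of 35 splits were as large for PFOA 1 mg/kg (51, highest other 84).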

How the results depend on the processing

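The alternatives that use array set, the array labelled wild type, PFOA 1 mg/kg, replicate 3 (here the doubtful array), missing values, the clock index and the silent-gene index were tests chosen only after the data were seen; the rest were planned. Of 285 calls of named genes, none reversed under any alternative. Centring on the 75th percentile kept 285, which tests little, because the deposited values already have equal quantiles on every array apart from missing values. The intensity trend kept 285, leaving out the dimmer probes all 261 still tested, the replicate block 280 and array set as a block 280. Leaving out the doubtful array kept 280, allowing missing values 257, the clock index together with array set as a block 252, the silent-gene index 238 and only the groups compared 105. The smaller array set alone kept 66 of the 178 it could test and the larger 73 of 285, and 168 kept their call whichever array was left out. The 1.5-fold minimum moved no count of probes by over 1.5 times, and neither did centring on the 75th percentile. Unless a reason is given, the cause was not tested.

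Counts of probes that moved by over 1.5 times, or to or from 0, follow by setting. "Wild type" and "null" stand for the response to the dose or compound named, and "genotype difference" for null minus wild type. Without the probes below the median, fewer probes share the adjustment: wild type PFOA 1 mg/kg 112, genotype difference 1 (PFOA 1 mg/kg), 174 (3 mg/kg) and 713 (pirinixic acid), null doses 1, null against wild type 51 on water and 117 on methylcellulose, null vehicles 1, both genotypes alike 58. With only the groups compared, fewer arrays estimate the variance: wild type 1, 441 and 70 (PFOA 1, PFOA 3, pirinixic acid), null PFOA 3 mg/kg 15, genotype difference 43 (pirinixic acid), doses 0 in wild type and 0 in null, PFOA against pirinixic acid 0 in wild type and 5 in null, null against wild type 17 and 3, wild type alike 42, both genotypes alike 6. With 1 probe per gene null PFOA 1 mg/kg gave 5 and the genotype difference 1. The intensity trend gave genotype differences of 1, 162 and 496, wild-type doses 14 and null against wild type on methylcellulose 72. Allowing missing values gave 205 for the genotype difference with pirinixic acid, 2 for the wild-type doses and 11 for null against wild type on water. The clock index with array set gave 4 for the wild-type doses, 1 for the null doses, 1 for PFOA against pirinixic acid in wild type and 10 for null against wild type on water.

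Within the smaller array set, with fewer arrays, the counts were 29 and 262 in wild type (PFOA 1 and 3 mg/kg), 1, 22 and 1 in null, 1 and 17 for the genotype differences with PFOA, 3 and 1 for the doses, 1 for PFOA against pirinixic acid in null, 7 and 0 for null against wild type, and 4 alike in both genotypes. Within the larger set they were 1 (PFOA 1 mg/kg) and 249 (pirinixic acid) in wild type, 0 and 4 in null with PFOA, 0 and 2 for the genotype differences with PFOA 3 mg/kg and pirinixic acid, 12 and 0 for the doses, 609 and 1 for PFOA against pirinixic acid, 2 and 0 for null against wild type, 8 for the null vehicles, 54 for wild type alike and 1 for both genotypes alike. Without the doubtful array, wild type PFOA 1 mg/kg gave 249, the genotype differences 41 and 178 with PFOA, the wild-type doses 2 and null against wild type 75 and 108; with array set as a block as well these were 283, 43, 201, 3, 77 and 127, the null doses 1 and the null vehicles 1. The silent-gene index gave 7 for null PFOA 1 mg/kg, 59 for the genotype difference with PFOA 3 mg/kg, 11 for the wild-type doses, 1 and 20 for PFOA against pirinixic acid, and 1 and 19 for null against wild type. The index without the doubtful array gave 236, null PFOA 1 mg/kg 10, genotype differences 41 and 601, wild-type doses 2, PFOA against pirinixic acid 5 and 21, null against wild type on water 52 and both genotypes alike 52.

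The replicate number as a block gave 588 for the genotype difference with pirinixic acid, 4 for the wild-type doses and 1 for PFOA against pirinixic acid in wild type, and moved no other count by over 1.5 times.

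Of 62 calls among 126 tests of gene lists, 10 passed with an estimated correlation and 39 with fry, which called 41 in all. Of 6 calls among 60 tests of marker lists, 0 and 5 passed, and fry called 8 in all. The other alternatives, apart from leaving out 1 array at a time, called 57 to 64 gene lists.

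Leaving out 1 array at a time gave 32 to 249 probes for wild type with PFOA 1 mg/kg, 825 to 1943 with 3 mg/kg and 797 to 2399 with pirinixic acid. Null mice had 2 to 3, 43 to 72 and 0 to 0. The genotype differences ran from 0 to 41, 42 to 145 and 144 to 626, the doses from 2 to 10 in wild type and 1 to 5 in null, and PFOA against pirinixic acid from 1 to 51 and 7 to 14. Null against wild type ran from 1 to 13 on water and 6 to 61 on methylcellulose, the vehicles from 0 to 4 and 0 to 1, wild type alike from 351 to 624, null alike from 0 to 0, both genotypes alike from 22 to 31, gene lists from 58 to 65 and marker lists from 5 to 7.

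Single arrays that moved a count by over 1.5 times, with the count without them, were these. For the genotype difference with PFOA 1 mg/kg they were the doubtful array (41) and wild type water 4 (1). For that with PFOA 3 mg/kg they were null PFOA 3 mg/kg 1 and 4 (49, 47), null water 1 to 4 (55, 56, 61, 55), wild type PFOA 3 mg/kg 2 to 4 (56, 57, 69) and water 2 to 4 (42, 61, 64). For that with pirinixic acid they were wild type pirinixic acid 1 and 3 (626, 169), methylcellulose 1 to 3 (150, 163, 161), null pirinixic acid 3 (205) and null methylcellulose 3 (144). The wild-type doses fell to 2 without the doubtful array, PFOA 1 mg/kg 4 or PFOA 3 mg/kg 3; the null doses went to 4 and 5 without PFOA 3 mg/kg 1 and 2, and to 1 without PFOA 1 mg/kg 1, 2 or 4 or PFOA 3 mg/kg 4. PFOA against pirinixic acid in wild type went to 51 without PFOA 3 mg/kg 1, 26 and 6 without pirinixic acid 3 and 1, 9 without water 1, and 1 without methylcellulose 2, PFOA 3 mg/kg 2, 3 or 4, or water 2 or 3; in null mice it fell to 7 without methylcellulose 3. Null against wild type gave 3, 5, 3 and 11 without null water 1 to 4 and 13, 6, 8 and 1 without wild-type water 1 to 4, and on methylcellulose 12, 14 and 6 without wild type 1 to 3 and 18, 17 and 21 without null 2 to 4. The vehicles gave 1 and 4 in wild type without methylcellulose 1 or water 1, and 1 in null without water 4; both genotypes alike gave 22 without null water 1.

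The log-scale alternative was not run, as the values are log2. Signal over background limits the dim probes: genes near the floor of the arrays, and the probes with missing values, can hide changes in either direction.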

Other observations

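The tests of replicate numbers against array set and of the clock index by group were chosen only after the data were seen.

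Some single genes were chosen after their values were seen, and no list was fixed or tested for them as a group. Ifi27l2b rose with PFOA in wild type (2.90 with 1 mg/kg and 4.30 with 3 mg/kg) and in null mice with 3 mg/kg (2.73), and also with pirinixic acid in wild type (2.95, adjusted p = 5.31e-05), while Ifitm3 fell in wild type with PFOA 3 mg/kg (-2.43) and pirinixic acid (-2.47). In null mice with PFOA 3 mg/kg, S100a8 rose by 7.44 on the log2 scale while S100a9, which codes for its usual partner protein, stood at -0.28 and did not pass, and Col1a1 rose by 3.10 while no other stellate cell marker passed. Whether these probes read their named transcripts alone was not tested.

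Array set went with the replicate number of the labels. Of the arrays numbered 1, 8 were in the smaller set and 2 in the larger; of those numbered 2, 0 and 10; of those numbered 3, 1 and 9; and of those numbered 4, 7 and 2. The labels give no batch or date, and what the sets are was not tested.

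The clock index differed between treated and vehicle groups by 1.41 (exact permutation p = 0.371) and 1.04 (p = 0.571) in wild type with PFOA 1 and 3 mg/kg, by -2.26 (p = 0.114) with pirinixic acid, and in null mice by 2.17 (p = 0.0571), 1.49 (p = 0.229) and 0.258 (p = 0.857), exact permutation tests throughout. None passed.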
